A study of Homo sapiens with 18 samples.

How the data were processed

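Serum microRNA (miRNA) was measured on 18 one-colour 3D-Gene arrays, 9 from mock-treated mice and 9 from cabozantinib-treated mice. RNA was extracted from serum with a liquid-sample reagent and labelled with Cy5, per the labels' protocols. The submitters' source field names the tumour cell line instead of serum, and the organism field names human although the serum is of mouse. The arrays carry probes for human miRNAs. Most abundant miRNAs have the same or nearly the same sequence in mouse and human, so the probes do not tell host miRNA from miRNA of the human xenograft.

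Each array's scanner table held 1 deposited intensity per spot on a linear scale, per the file headers, with no background column. The scanner, its settings and any background handling are not given in the sources used here. Each array had 2632 human miRNA probes, 312 blank spots, 112 spots without a probe and 16 spike control spots. Of the probes, 2616 carried 1 miRNA name and 16 carried several. The authors' processed table held intensity values for 1041 probes on every array, from 0.296 to 45330 with a median of 13.2 in each column. Sorted values were identical across the 18 columns and followed the ranks of the scanner values on each array, with a lowest rank correlation of 1.00. That table is therefore linear, quantile-normalized over the probes with values and not centred per probe. The authors' background step is not given in the sources used here. All of its value columns could be matched to an array.

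Scanner intensities were corrected with normexp (offset 50, fitted on all spots) and the human probes were quantile-normalized between arrays in limma 3.58.1 under R 4.3.3. A probe was called detected on an array above the mean plus 2 SD of that array's blank spots. Probes detected on at least 9 of the 18 arrays were kept, which left 1446. The groups were compared on the log2 scale with lmFit and eBayes, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. All fold changes are on the offset scale, which understates changes, most of all those of dim probes. No array shared its values with another, with 0 identical pairs.

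In all, 16 lists of miRNAs were fixed before the data were examined. They covered miRNAs of red cells, hepatocytes, leukocytes, muscle and endothelium, the C19MC, miR-371 to miR-373, miR-17-92, let-7, miR-200 and 14q32 families or clusters, p53-responsive and MET-targeting miRNAs, miRNAs raised or lowered in hepatocellular carcinoma, and miRNAs with a miRBase number of 4000 or above. Lists with at least 3 kept members, 15 of the 16, were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it. Detection was compared with Fisher's exact test, two-sided, over probes detected on some but not all arrays. Array-level measures and a haemolysis index (log2 miR-451a minus log2 miR-23a-3p) were compared with exact two-sided permutation tests of the difference in means.

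The rule for miRNAs named in the text was also fixed beforehand. It took up to 12 called miRNAs per direction by size, the 10 smallest unadjusted p values where fewer than 10 were called, the 3 brightest kept members and up to 4 called members of each list, and miR-451a, miR-23a-3p and miR-122-5p. That rule named 55 miRNAs. A further 11, called without the array mock 7 at 1.2-fold or more, were added after their values were seen.

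The alternatives set beforehand changed the background correction, the normalization, the filter, the source of values, the prior variance, array weights, the test, the inter-gene correlation and the detection limit, used the replicate number as a block, or left out each array in turn. Others were added after the data were seen. They used a detection limit from the spots without a probe, scaling by the spike control spots, the haemolysis index as a covariate, and combinations of a setting with the removal of mock 7. On simulated data with the 18 arrays' spread, 88 of 100 changes of 0.50 and 100 of 100 changes of 1 on the log2 scale were recovered, with 6 false calls among 194 over 1446 probes. With the spread of the 17 arrays without mock 7, 99 of 100 and 100 of 100 were recovered, with 11 false calls among 210. Data simulated without changes gave 0 calls. The simulated noise was independent between probes, while a random split of the 17 real arrays gave up to 19 calls. The shares recovered are over all probes and do not hold for variable miRNAs such as miR-16-5p (SD 0.98 in 9 mock arrays).

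The labels give 9 mice per group but do not tie each array to a mouse, so p values measure the spread between these samples. No genome or coordinate is used here, and miRNAs are named as in the array's own annotation. The number of arrays limits the precision.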

Results

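The series profiled miRNAs in the serum of nude mice that carried subcutaneous xenografts of Hep3B-LR, a lenvatinib-resistant derivative of the human hepatocellular carcinoma line Hep3B. Lenvatinib and cabozantinib are oral multikinase inhibitors used in liver cancer, and cabozantinib inhibits MET, VEGFR2 and AXL. Mice were 8 weeks old and were assigned to treatment when the shortest diameter of the xenografts averaged 6 mm. The treated group received 1200 µg of cabozantinib in 150 µL of DMSO by mouth 5 times a week, and the mock group received DMSO alone. The labels give 9 mice and 9 arrays per group. The study's title concerns growth of lenvatinib-resistant hepatoma cells and the liver enzyme gene FTCD, which a miRNA array does not measure. The comparison made here asks which circulating miRNAs differed between treated and mock mice.

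Between 954 and 1986 probes per array, with a median of 1467, exceeded the limit set by blank spots. Blank spots averaged 55.4 to 60.8 units of scanner brightness, and the brightest spot of an array reached 37174 to 55230. The blank limit was permissive, since 79.5 to 100% of spots without a probe also exceeded it. The array mock 7 stood apart from the other 17. Its 90th percentile of probe brightness was 432, against 84.0 to 110.5 elsewhere, and it had 1986 detected probes against 954 to 1573. Its mean correlation with its own group was 0.80, against 0.957 to 0.992 for the other arrays with theirs. The first principal component held 68.2% of the variance, and mock 7 scored 23.4 on it against -4.18 to 2.45 for the others. Results are therefore given with all 18 arrays, as planned, and the calls and lists also with 17.

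**Figure D1:**
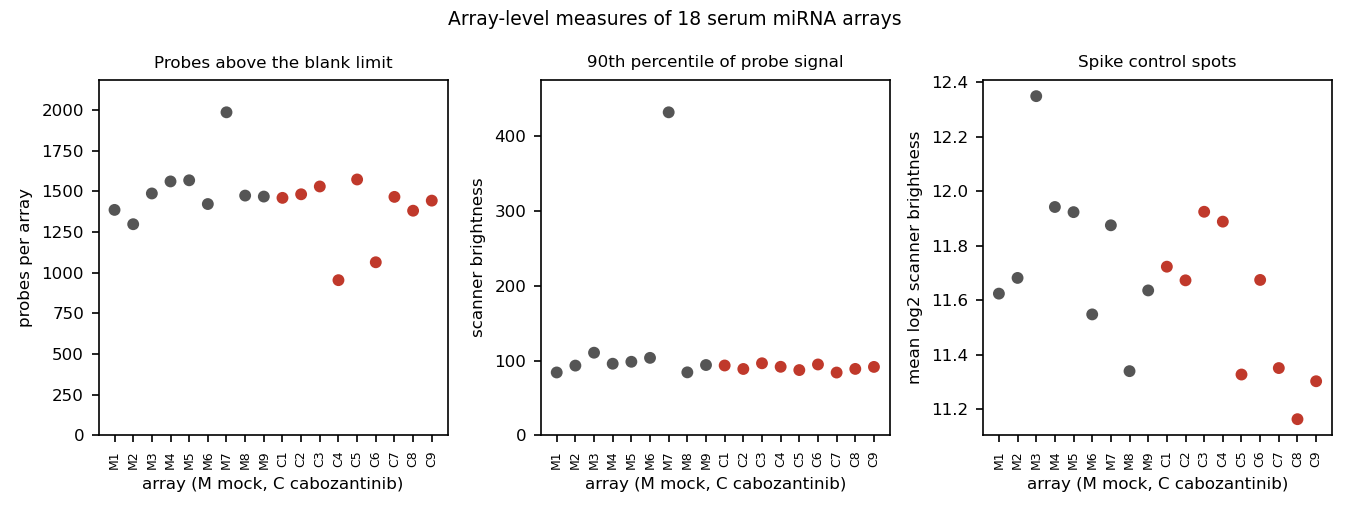
Probes above the blank limit, 90th percentile of probe brightness and mean log2 brightness of the spike control spots, 1 point per array (grey, mock; red, cabozantinib). The array mock 7 lies at 1986 probes and at a 90th percentile of 432, while its spike controls lie among those of the other arrays.

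Serum of cabozantinib-treated mice held less of both strands of miR-126, a miRNA abundant in endothelial cells, and more miR-210-3p, a miRNA induced in hypoxia. miR-126-3p fell from 7.99 ± 0.58 to 7.07 ± 0.20 (log2 normalized intensity, mean ± SD, n = 9 per group), which is 1.89-fold lower, and miR-126-5p was lower. miR-142-5p, a miRNA of blood cells, was 1.60-fold lower, and miR-10a-5p, encoded in a HOX gene cluster, was lower. miR-10a-5p exceeded the limit from spots without a probe on 9 of 9 mock and 0 of 9 cabozantinib arrays, and miR-126-5p on 9 of 9 and 3 of 9, so the sizes of their changes are uncertain. miR-210-3p rose from 6.98 ± 0.37 to 7.68 ± 0.27 (n = 9 per group), or 1.62-fold. Its lowest normalized mock value (6.34) was on mock 7, where its scanner brightness (289) was the highest of all arrays. Without mock 7 the rise was 1.52-fold. miR-375-3p, a miRNA of pancreatic islets and secretory epithelia, rose from 6.40 ± 0.28 to 6.99 ± 0.20 (n = 9 per group).

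With limma and all 18 arrays, 7 of 1446 miRNAs passed the adjusted threshold, 3 higher and 4 lower with cabozantinib, and 160 had an unadjusted p under 0.05. A rank-sum test called 0, with 177 at an unadjusted p under 0.05. The smallest p that an exact rank-sum test can give with 9 arrays per group is 4.11e-05. A single fully separated probe among 1446 could therefore not pass, and 0 were separated after normalization. The log2 difference was -0.92 for miR-126-3p (SE 0.197, adjusted p = 0.046), -0.68 for miR-142-5p (SE 0.140, adjusted p = 0.046) and -0.31 for miR-126-5p (SE 0.067, adjusted p = 0.046). It was -0.23 for miR-10a-5p (SE 0.043, adjusted p = 0.037), 0.69 for miR-210-3p (SE 0.146, adjusted p = 0.046) and 0.59 for miR-375-3p (SE 0.110, adjusted p = 0.037). For each of these, all 9 cabozantinib arrays lay on the same side of the mock mean. The last call, miR-4489, differed by 0.07 (SE 0.014, adjusted p = 0.046) at a median brightness of 64.9 in mock and 65.9 in cabozantinib arrays, near the level of spots without a probe, and its difference was -0.071 without normalization between arrays. The next miRNAs by p did not pass. They included miR-10b-5p at -0.42 (adjusted p = 0.054) and miR-142-3p at -0.46 (adjusted p = 0.057), sizes that are uncertain, since 3 of 9 and 2 of 9 cabozantinib arrays exceeded the limit from spots without a probe, and miR-223-3p, a myeloid miRNA, at -0.55 (adjusted p = 0.086). The other 7 of the 10, namely miR-339-3p, miR-214-5p, miR-1269a, miR-1298-5p, miR-138-5p, miR-141-3p and miR-6742-5p, exceeded that limit on 0 to 6 of 18 arrays, so no sizes are given for them.

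The calls with 18 arrays lay close to the threshold. With the replicate number as a block 0 miRNAs were called (126 at an unadjusted p under 0.05 in limma). Removing any 1 of mock 1, 2, 4 and 6 or of cabozantinib 1, 2, 3, 4, 6 and 7 left 0 calls in limma, with 117 to 166 miRNAs at an unadjusted p under 0.05, and removing mock 5, mock 8, mock 9, cabozantinib 5 or cabozantinib 9 left 2, 4, 2, 1 and 2.

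**Figure D2:**
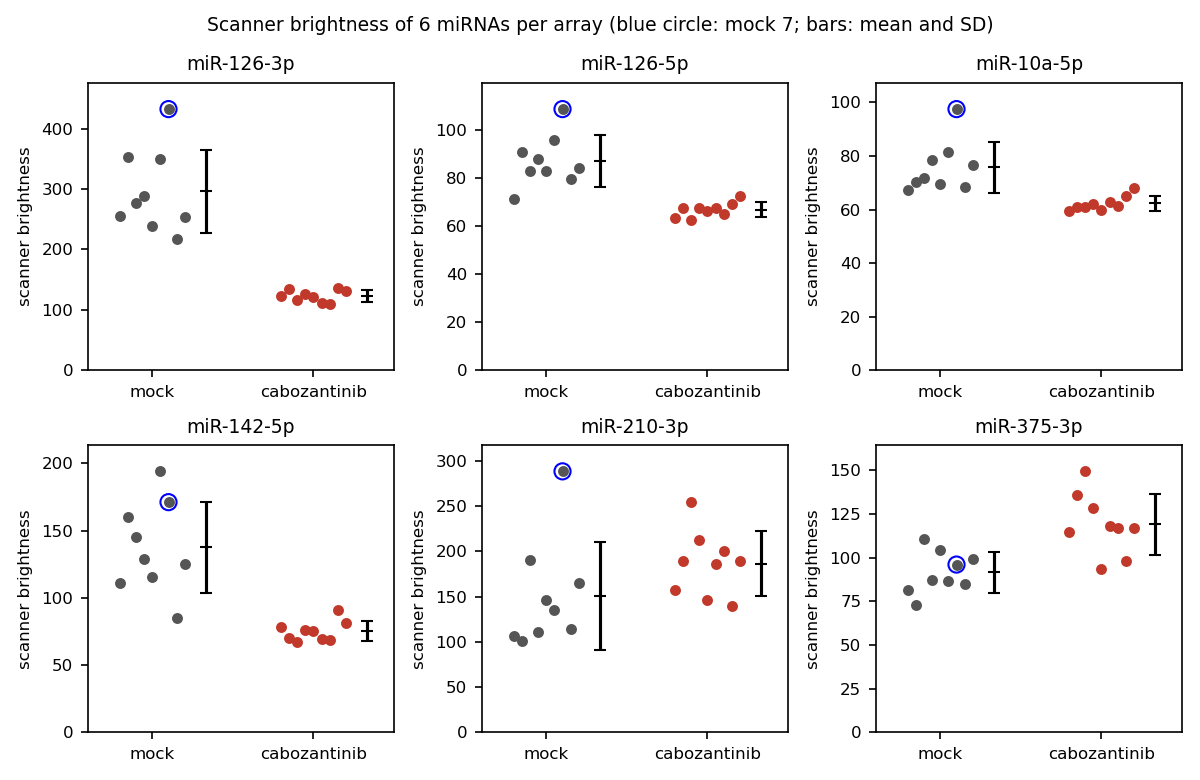
Scanner brightness before normalization of 6 miRNAs called with 18 arrays, 1 point per array (grey, mock; red, cabozantinib; blue circle, mock 7), with the mean and SD of each group. For miR-126-3p the 9 mock arrays lie at 217 to 432 and the 9 cabozantinib arrays at 110 to 136.

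The scanner values of miR-126-3p did not overlap between the groups. They were 217 to 432 in mock and 110 to 136 in cabozantinib arrays before any scaling between arrays. In all, 7 of 1446 probes were dimmer on every cabozantinib array than on every mock array, and 0 were brighter. Chance separates 0.00411% of probes in one direction or the other, or 0.0595 probes here. That figure does not allow for probes that vary together or for whole arrays that differ in brightness. Without normalization between arrays, 77 miRNAs were lower and 1 higher at an unadjusted p under 0.05 in limma. let-7i-5p, miR-10b-5p, miR-195-5p and miR-199a-5p were among the 7 separated probes, with miR-152-3p and miR-497-5p, which were named after their values were seen. The gap was narrow for let-7i-5p (lowest mock value 106.8, highest cabozantinib value 106.5) and miR-199a-5p (95.5 and 95.1). After quantile normalization 0 probes were separated in either direction with 18 arrays, while without mock 7 it was 5 lower and 1 higher of 1410, against 0.116 by chance.

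Without mock 7, a choice made after the data were seen, lower levels extended to further miRNAs. The names added here beyond the fixed rule were chosen after their values were seen. miR-126-3p was 2.11-fold lower, at 8.00 ± 0.23 in 8 mock and 6.93 ± 0.19 in 9 cabozantinib arrays. miR-16-5p, abundant in red cells, was 1.86-fold lower, and miR-21-5p, widely expressed and often raised in tumours, was 1.66-fold lower. let-7i-5p was 1.58-fold and miR-15a-5p 1.53-fold lower. The myeloid miR-223-3p was 1.45-fold lower, and of the smooth muscle miRNAs miR-143-3p was 1.42-fold lower and miR-145-5p lower, with 4 of 9 cabozantinib arrays above the limit from spots without a probe. These 3 and other lowered miRNAs were high on some arrays where skeletal muscle miRNAs were bright (values normalized with 18 arrays). miR-223-3p was 7.57 and 7.46 on mock 1 and 2, where miR-133a-3p was 8.39 and 9.43, against 6.58 to 6.75 on the other mock arrays. Among mock arrays miR-16-5p (10.44 and 10.81), miR-15a-5p (8.01 and 8.32), miR-195-5p and miR-199a-3p/miR-199b-3p were also highest on mock 1 and 2. miR-145-5p was not, at 6.22 on mock 1, and miR-143-3p was as high on mock 9 as on mock 2 (7.17). Mock 1 and 2 also had the highest haemolysis indices of all arrays (3.99 and 4.31). These mock values therefore do not tell a link with muscle miRNAs from one with red-cell miRNAs. Cabozantinib 8 and 9 had indices of 2.05 and 1.64, which were not the highest of their group. In the cabozantinib group miR-223-3p, miR-143-3p and miR-145-5p were highest on arrays 8 and 9, where miR-133a-3p was 7.06 and 8.00, against 5.71 to 5.81 on the others. So were miR-142-5p (6.61 and 6.36) and miR-10a-5p (5.94 and 5.95), both called with 18 arrays, and miR-142-3p, miR-22-3p, miR-199a-5p and miR-7162-3p. miR-21-5p did not follow, with cabozantinib 4 (9.86) above cabozantinib 8 (9.70) and mock 6 highest in its group. miR-210-3p was 1.52-fold and miR-375-3p 1.40-fold higher.

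In limma, 39 of 1410 miRNAs passed without mock 7, 10 higher and 29 lower, and all 7 calls of the 18 arrays were among them. The excess of lower calls depended on the scaling, with 10 higher and 9 lower under spike scaling and 3 higher and 24 lower under median scaling. The log2 difference of miR-126-3p was -1.08 (SE 0.098, adjusted p = 9.65e-06), lower than the mock mean on 9 of 9 cabozantinib arrays. It was -0.89 for miR-16-5p (SE 0.224, adjusted p = 0.042), -0.73 for miR-21-5p (SE 0.172, adjusted p = 0.030) and -0.66 for let-7i-5p (SE 0.108, adjusted p = 0.0033). For miR-142-5p it was -0.72 (SE 0.098, adjusted p = 5.33e-04), and for miR-210-3p 0.60 (SE 0.128, adjusted p = 0.020). Other lowered miRNAs of 1.2-fold or more were miR-7162-3p, miR-199a-3p/miR-199b-3p, miR-142-3p, miR-22-3p, let-7g-5p, miR-10b-5p, miR-195-5p, miR-199a-5p, miR-6088 and miR-126-5p, at -0.75 to -0.32. Only miR-210-3p and miR-375-3p were raised by 1.2-fold or more, and 18 of the 39 calls changed by less than 1.2-fold. Scaling by the spike control spots moved the median of all miRNAs by 0.12 with 18 and by 0.18 with 17 arrays. Under it 2 and 19 miRNAs were called.

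With the preset correlation camera called 5 of 15 lists with 18 arrays and 9 without mock 7, and with an estimated correlation 0 and 0, with 1 and 2 lists at an unadjusted p under 0.05. At least 5 lists were called in 84 of 100 splits of the 18 arrays. fry, which asks whether members move one way on balance, called 0 of 15 with 18 arrays (4 at an unadjusted p under 0.05) and 6 without mock 7. Leukocyte miRNAs were lower as a list with camera's preset correlation (fry adjusted p = 0.104 with 18 arrays and 0.0039 without mock 7). Of 8 leukocyte miRNAs, 1 fell and 7 did not pass, and 4 fell when adjusted over the list alone. The median log2 difference was -0.17 (camera adjusted p = 3.78e-04, and adjusted p = 0.328 with an estimated correlation). Differences were negative for 6 members and positive for 2. miR-146a-5p, among the brightest members, differed by 0.0051, and by -0.085 without mock 7. Of 9 leukocyte probes 6 exceeded the limit from spots without a probe on 9 arrays or more. Without mock 7, miR-142-5p, miR-223-3p and miR-142-3p fell among 7 members, 5 when adjusted over the list alone, and the median was -0.24 (adjusted p = 2.66e-05, and adjusted p = 0.142 with an estimated correlation). Of 9 erythrocyte miRNAs, 0 passed in limma with 18 arrays, over all miRNAs or adjusted over the list alone, and 2 were lower at an unadjusted p under 0.05 (median -0.22, camera adjusted p = 0.277), and miR-451a, the most abundant red-cell miRNA, differed by -0.55 (SE 0.491, adjusted p = 0.728). Without mock 7, miR-16-5p fell, as did 2 members adjusted over the list alone, and the median was -0.22 (camera adjusted p = 0.020, and adjusted p = 0.291 with an estimated correlation). The haemolysis index differed by -0.61 with 18 arrays and by -0.73 without mock 7 (exact permutation p = 0.160 and p = 0.118).

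The endothelial and angiogenic miRNAs did not pass as a list with 18 arrays. Of 12 members, miR-210-3p rose, miR-126-3p and miR-126-5p fell and 9 did not pass, with 2 raised and 2 lowered when adjusted over the list alone. miR-23b-3p differed by 0.31, miR-27b-3p by 0.36 and miR-23a-3p by 0.06, none past the threshold, and these turned to -0.063, -0.024 and -0.33 without normalization. Without mock 7 they were 0.09, 0.16 and -0.13. The median was 0.03 (camera adjusted p = 0.776). Without mock 7, 1 member rose and 3 fell, with 2 raised and 3 lowered adjusted over the list alone, and the median was -0.10 (adjusted p = 0.024, and adjusted p = 0.291 with an estimated correlation). The direction of this list also turned with median scaling (-0.13), spike scaling (-0.10) and no normalization (-0.31).

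The let-7 family, miRNAs with shared targets such as RAS genes, did not pass as a list with 18 arrays and was lower without mock 7. Of 9 members 0 passed in limma with 18 arrays (2 lower at an unadjusted p under 0.05), 1 fell adjusted over the list alone, and 8 of 9 had negative differences, with a median of -0.21 (camera adjusted p = 0.055). Without mock 7, let-7i-5p and let-7g-5p fell, 7 of 9 fell adjusted over the list alone, and all 9 differences were negative, with a median of -0.39 (camera adjusted p = 3.77e-08, and adjusted p = 0.142 with an estimated correlation). let-7f-5p, let-7a-5p and let-7d-5p, the brightest members, differed by -0.49, -0.39 and -0.40 without mock 7 and did not pass over all miRNAs. On mock 1 and 2 muscle miRNAs were bright and the haemolysis index was highest (values normalized with 18 arrays). They were the highest mock arrays for let-7f-5p (9.17 and 9.02), let-7d-5p (8.98 and 8.90) and let-7g-5p (7.47 and 7.60). This did not hold for let-7a-5p and let-7i-5p, where mock 5 and mock 9 exceeded mock 1.

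Hepatocyte miRNAs and the miR-17-92 family were higher as lists only with camera's preset correlation. With fry the adjusted p was 0.118 and 0.503 with 18 arrays, and 0.056 and 0.358 without mock 7. In limma with 18 arrays 0 members of either list were called singly, over all miRNAs or adjusted over the list alone. At an unadjusted p under 0.05, 2 members of each were higher. All 8 hepatocyte miRNAs had positive differences, with a median of 0.25 (camera adjusted p = 7.21e-04, and adjusted p = 0.328 with an estimated correlation). Among them miR-194-5p differed by 0.68, miR-192-5p by 0.62 and miR-122-5p, the main hepatocyte miRNA, by 0.23 (SE 0.260, adjusted p = 0.783), and without mock 7 these were 0.35, 0.35 and 0.04. All 15 miR-17-92 members, which come from polycistrons active in proliferating cells, had positive differences, with a median of 0.37 (camera adjusted p = 3.30e-05, and adjusted p = 0.573 with an estimated correlation). Its brightest members miR-106a-5p, miR-17-5p and miR-20a-5p differed by 0.44, 0.46 and 0.53, and by 0.09, 0.13 and 0.19 without mock 7. The array mock 7 moved with both lists, since without it the medians were 0.11 (adjusted p = 0.0056) and 0.12 (adjusted p = 0.014), with an adjusted p = 0.291 and 0.626 with an estimated correlation. Without it miR-885-3p, named after its values were seen, rose by 0.04, over all miRNAs and adjusted over the list alone, and was above the level of spots without a probe on 1 array. Of the 15 miR-17-92 members 0 did in limma, with 2 higher at an unadjusted p under 0.05.

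With camera's preset correlation the epithelial miR-200 family was higher by a small amount (fry adjusted p = 0.104 with 18 arrays and 0.029 without mock 7). The 14q32 list lay near background and its direction is not settled. Of 9 miR-200 probes 3 exceeded the limit from spots without a probe on 9 arrays or more, and of 46 probes of 14q32 it was 4. Of 6 miR-200 members 0 passed over all miRNAs in limma with 18 arrays (4 higher at an unadjusted p under 0.05) and 3 rose adjusted over the list alone, with a median of 0.09 (camera adjusted p = 1.74e-05, and adjusted p = 0.328 with an estimated correlation). miR-200b-3p differed by 0.33 and miR-200a-3p by 0.32, while miR-429 differed by 0.10. Without mock 7 the median was 0.06 (adjusted p = 4.21e-04, and adjusted p = 0.200 with an estimated correlation), and miR-141-3p passed, with 3 raised adjusted over the list alone. miR-141-3p exceeded the level of spots without a probe on 0 of 18 arrays, so no size is given for it. Of 27 members of 14q32, an imprinted cluster, 0 passed either way in limma (5 lower at an unadjusted p under 0.05), 22 had negative differences, and the median was -0.014 (camera adjusted p = 0.0023, and adjusted p = 0.573 with an estimated correlation). Without mock 7 it was -0.014 (adjusted p = 2.66e-05, and adjusted p = 0.200 with an estimated correlation). Its direction turned with median scaling (0.13), spike scaling (0.16) and the limit from spots without a probe (0.043).

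**Figure D3:**
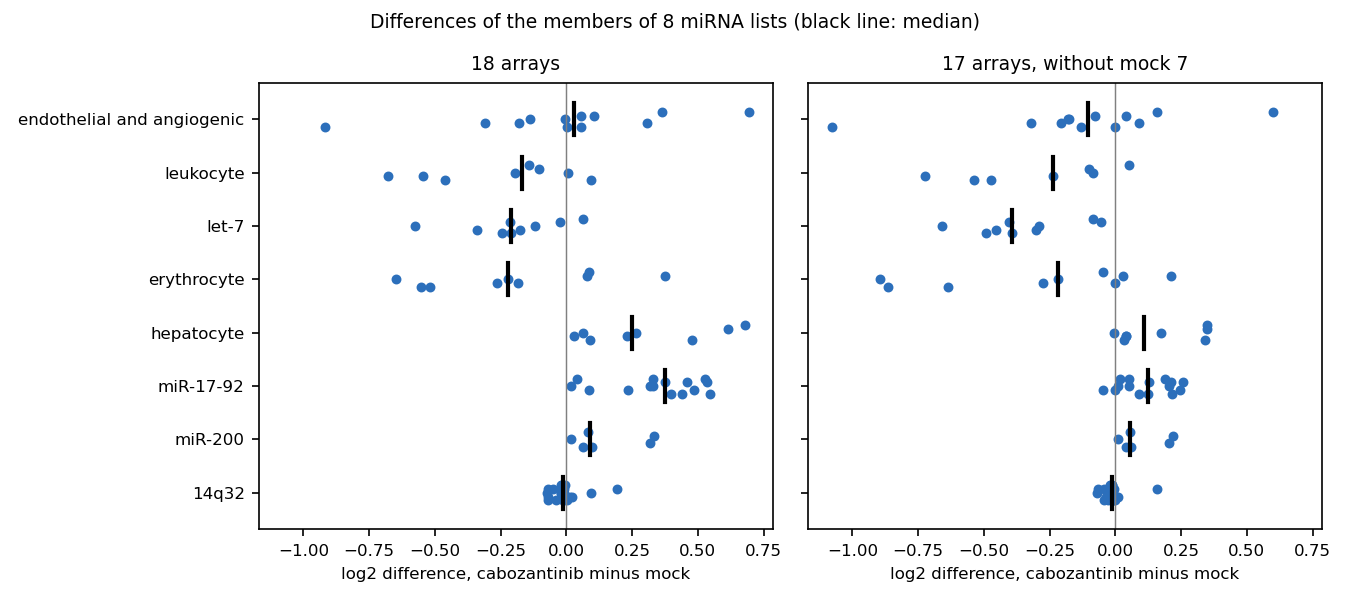
Log2 difference, cabozantinib minus mock, of each kept member of 8 miRNA lists (points) with the list median (black line), with 18 arrays at left and without mock 7 at right. The miR-17-92 median lies at 0.37 with 18 arrays and at 0.12 without mock 7, and the let-7 median at -0.21 and -0.39. The endothelial and 14q32 medians change sign under spike or median scaling.

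The remaining lists were not called with 18 arrays. The median difference was 0.03 for p53-responsive miRNAs (camera adjusted p = 0.470), of which miR-215-5p differed by 0.66 (0.41 without mock 7), and 0.02 for MET-targeting miRNAs (adjusted p = 0.676), of which miR-144-3p differed by -0.52. The mean of the MET-targeting members was -0.010, and the direction of that list turned with median scaling, spike scaling and no normalization. For miRNAs raised in hepatocellular carcinoma, among them miR-21-5p at -0.52, the median was 0.08 (adjusted p = 0.606), with the direction turned by median scaling and by no normalization, and for those lowered in it -0.023 (adjusted p = 0.389). In the list of those lowered 1 of 18 members rose, which was miR-375-3p, with 2 raised and 5 lowered adjusted over the list alone. Without mock 7 it was called lower, with a median of -0.08 (adjusted p = 0.0011, and adjusted p = 0.200 with an estimated correlation), and 1 member rose and 5 fell, with 2 raised and 8 lowered adjusted over the list alone. The p53, MET and raised lists had 0, 0 and 0 members past the threshold over all miRNAs in limma with 18 arrays, and 4, 2 and 4 at an unadjusted p under 0.05. Adjusted over the list alone, 2 p53-responsive members fell, 1 MET-targeting member rose and 1 fell, and 1 member of the raised list fell. Without mock 7, camera's direction turned to lower for these 3 lists, none of them called. The medians were 0.0084 (adjusted p = 0.979), -0.0041 (adjusted p = 0.675) and 0.016 (adjusted p = 0.609). Of the p53-responsive members miR-143-3p and miR-145-5p fell, of the MET-targeting members miR-199a-3p/miR-199b-3p, and of 14 in the raised list miR-21-5p, miR-10b-5p and miR-500a-3p, the last named after its values were seen. Adjusted over the list alone, 1 rose and 2 fell, 1 rose and 1 fell, and 0 rose and 3 fell. The C19MC cluster, which is specific to primates, had a median of 8.18e-04 (adjusted p = 0.569), with miR-1323, miR-498-5p and miR-518b among 7 kept members. The cluster of miR-371 to miR-373 had a median of -0.022 (adjusted p = 0.277). In limma 0 members of either passed over all miRNAs or adjusted over the list alone, with 0 and 1 at an unadjusted p under 0.05. Without mock 7 the medians were 0.0013 and -0.010 (adjusted p = 0.751 for both), again with 0 members past either threshold in limma and 0 and 0 at an unadjusted p under 0.05. Of 722 kept miRNAs numbered 4000 or above, 1 passed, miR-4489, and 0 did adjusted over the list alone, with a median of -0.0059 (adjusted p = 0.070). Without mock 7, 3 of 707 rose and 3 fell, 3 and 2 adjusted over the list alone, and the median was 0.0011, with camera's direction turned to higher (adjusted p = 0.570). miR-4454 was the brightest probe on every array, so quantile normalization gave it the same value throughout and its difference of 0 is fixed by that step. The muscle list kept 2 members and was not tested. miR-133b and miR-133a-3p differed by -0.21 (SE 0.507) and -0.32 (SE 0.526).

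In the planned comparison the red-cell index and the measures of array quality did not differ past a threshold. The index does not measure carry-over of leukocytes or platelets. The haemolysis index was 2.83 ± 1.08 in mock and 2.22 ± 0.61 in cabozantinib arrays (n = 9 per group, difference -0.61, exact permutation p = 0.160, adjusted p = 0.360 over 6 measures). It differed by -1.14 with cyclic loess (exact permutation p = 0.035) and by -0.86 without mock 6 (exact permutation p = 0.026), where the p ran from 0.035 to 0.162 over the other settings and from 0.026 to 0.307 with 1 array left out. Probes detected per array differed by -144 (exact permutation p = 0.180), median brightness by -1.23 (exact permutation p = 0.439), blank level by -0.20 (exact permutation p = 0.800) and spike controls by -0.21 on the log2 scale (exact permutation p = 0.140). Without mock 7 the first 3 of these were -85.4, -0.12 and 0.041, and without cabozantinib 4 the probe count differed by -91.8. Fisher's exact test of detection called 0 of 1237 probes, with 18 at an unadjusted p under 0.05, each detected on more mock than cabozantinib arrays. Single arrays bear on that direction, since mock 7 had 1986 detected probes and cabozantinib 4 and 6 had 954 and 1064, with a blank SD of 1.17 and 1.15 against 0.29 to 0.61 elsewhere. With the stricter limit from spots without a probe, chosen after the data were seen, 1 of 679 was called. It was miR-10a-5p, above that limit on 9 of 9 mock and 0 of 9 cabozantinib arrays (Fisher's exact test, adjusted p = 0.028).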

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

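The tests of mock 7 and of its part in the list shifts were chosen after the results were seen, unlike the splits of the arrays. In 36 of 144 groups of 9 arrays, 1 array stood farther from the rest than Dixon's limit allows. Chance alone would give about 7.2 such groups, and 28 of the 36 were mock 7.

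Mock 7 had 1986 detected probes, against at most 1568 on another mock array, and a median brightness of 68.8 against at most 61.3. After normalization it lay below the other mock arrays for miR-126-3p (6.56), miR-92a-3p (6.63), miR-194-5p (7.57), miR-192-5p (7.72), miR-23b-3p (7.08), miR-27b-3p (6.996), miR-23a-3p (7.10) and miR-106a-5p (8.29). The same held for miR-17-5p (8.31), miR-20a-5p (8.02), let-7f-5p (6.44), let-7a-5p (6.93), let-7d-5p (6.79), let-7g-5p (6.12), miR-200b-3p (5.88), miR-21-5p (8.34), miR-22-3p (6.63) and miR-26a-5p (6.93). It also lay lowest for miR-29b-3p (6.48), miR-487b-3p (5.91), miR-7975 (12.44) and miR-7977 (11.22). It lay above the other mock arrays for miR-498-5p (5.81), miR-371b-5p (6.40), miR-1185-1-3p (6.60) and miR-6088 (10.73). Before normalization the direction was the opposite for some miRNAs on which it lay lowest, since mock 7 was then the brightest of all 18 arrays. These were miR-126-3p (scanner brightness 432), miR-92a-3p (465), miR-23a-3p (808), let-7a-5p (651), miR-21-5p (2271), miR-22-3p, miR-23b-3p, miR-27b-3p and let-7d-5p, so the low normalized values do not show that this serum held less of them. miR-210-3p, not flagged by Dixon's limit, went the same way (6.34 after normalization, scanner brightness 289).

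In scanner brightness above blank, mock 7 exceeded the median of the other arrays 142-fold for miR-4732-5p, 70.3-fold for miR-6088 and 65.4-fold for miR-1246, but reached 0.51 times it for miR-1260b, all named after their values were seen. Its spike controls lay 0.74 SD from the other 17 arrays, which argues against a brighter scan of the whole array, and its haemolysis index of 2.09 lay inside the 0.77 to 4.31 of the other 8 mock arrays, which argues against red-cell lysis. The interquartile range of its log2 ratios over 141 bright probes was 3.71, against at most 0.67 on another array, which argues against more RNA of the same make-up. A serum with a different RNA make-up or a fault in labelling or hybridization remain possible, were not tested, and no biological explanation was tested within the group.

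The shifts of the 5 lists called with 18 arrays depended in part on mock 7, which may account for those of the miR-17-92 and hepatocyte lists. Without it their medians were 0.335 and 0.435 times as large. The ratio was 0.63 for miR-200, 1.40 for leukocyte and 1.03 for 14q32 miRNAs, with a median of 0.63, so the array does not account for all 5 shifts alike. In 84 of 100 splits of the 18 arrays as many lists were called, up to 12 in another split, so chance cannot be excluded for that count, and why other splits call as many was not tested. For the 9 lists without mock 7, 2 of 100 splits gave as many, with 9 as the highest other, so a random split rarely gave that count with the preset correlation. With an estimated correlation 0 of 15 lists were called.

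Within the cabozantinib group, array 8 stood apart for miR-10b-5p (6.42) and miR-7162-3p (7.26), array 9 for miR-133b (8.43), miR-518b (5.79) and miR-494-3p (7.43), array 6 for miR-17-5p (11.78), and array 2 for miR-7975 (12.93) and miR-7977 (14.49), whose values on the other 8 arrays are equal because quantile normalization assigns them by rank. Of the spots without a probe, which measure no miRNA, 79.5% or more exceeded the blank limit on every array.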

How the results depend on the processing

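The settings with the limit from spots without a probe, the spike control spots or the haemolysis index, and every setting that joins the removal of mock 7 to another change, were chosen after the data were seen. Differences are log2, cabozantinib minus mock, and list values are medians. A list's direction is that of camera, relative to all other miRNAs, and can differ in sign from its median. Of the 7 called miRNAs, all but miR-4489 kept their sign under each of their alternatives, but each of the 7 lost its call under some. The adjusted p ran from 8.69e-11 to 0.350 for miR-126-3p, from 1.40e-04 to 0.767 for miR-142-5p and from 5.10e-05 to 0.430 for miR-210-3p. It reached 0.780 for miR-10a-5p and 0.767 for miR-126-5p, miR-375-3p and miR-4489. Sizes also moved, from -1.59 to -0.056 for miR-10a-5p, from -1.39 to -0.17 for miR-126-5p and from 0.38 to 1.11 for miR-210-3p. They ran from -1.57 to -0.84 for miR-126-3p, from -1.84 to -0.56 for miR-142-5p and from 0.40 to 1.44 for miR-375-3p. Low signal over background is a limit, since 491 of 2632 probes passed the stricter detection limit.

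The count of called miRNAs, 7 with all arrays, was 13 with offset 16, 11 with median scaling, 22 without normalization, 58 with array weights, 16 with an intensity trend and robust prior, and 2 with spike scaling. It was 0 with cyclic loess, no filter, rank sums and the haemolysis covariate (44, 212, 177 and 121 at an unadjusted p under 0.05). The split of higher against lower calls was 1 to 10 with median scaling, 1 to 21 without normalization and 1 to 1 with spike scaling, against 3 to 4. Leaving out 1 array gave 0 to 39, or 0 to 10 apart from mock 7. Without mock 7, the count was 39, then 19 with spike scaling (10 higher, 9 lower), 27 with median scaling (3 higher, 24 lower), 52 with blank subtraction, 17 with the haemolysis covariate and 31 with the no-probe limit. The 5 called lists became 9 without normalization or with spike scaling and 0 with an estimated correlation, and leaving out 1 array gave 5 to 9. Without mock 7, the 9 called lists became 8 with the haemolysis covariate, 7 with median scaling or the replicate block, 4 of 13 with the no-probe limit and 0 with an estimated correlation. The haemolysis difference was -1.14 with cyclic loess and ran from -0.86 to -0.41 with 1 array left out. The background difference ran from -0.60 to 0.097. Detection calls were 1 with the no-probe limit. The cause of these changes was not tested.

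With the replicate number as a block, 0 miRNAs were called (126 at an unadjusted p under 0.05), and 14 without mock 7 (7 higher, 7 lower). Lists called stayed at 5, and the haemolysis difference stayed at -0.61. Same-numbered arrays correlated above 0.1 in 4 of 9 pairs, and 1 of 9 mock arrays correlated best with its own number, so the numbers are not taken to pair mice. Blank levels of same-numbered arrays did correlate (r = 0.78, exact permutation p = 0.013, adjusted p = 0.066). Blank level rose with the number in both groups, though not in strict order. It went from 55.4 on mock 1 to 60.3 on mock 9, and from 56.0 on cabozantinib 1 to 60.8 on cabozantinib 9. Whether the number marks a shared array run is not given by the labels and was not tested. Such a run would not need paired mice, so the 0 calls with the block remain a limit.

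The remaining values changed direction. All but 9 of them had neither value past the threshold. The 9 were the endothelial list (5 settings, leaving out mock 7 among them), the 14q32 list (3) and miR-4489 (1). The cause was not tested.

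Median scaling gave the endothelial and angiogenic list -0.13, the MET-targeting list 0.13, the raised in hepatocellular carcinoma list 0.13, the 14q32 list 0.13, miR-214-5p 0.075, miR-138-5p 0.075, miR-146a-5p -0.061, miR-23a-3p -0.16, miR-498-5p 0.10, miR-371b-5p -0.074, miR-371b-3p 0.019, miR-29b-3p -0.20, miR-494-3p -0.012 and miR-7975 -0.036. No normalization gave the endothelial and angiogenic list -0.31, the MET-targeting list -0.051, the raised in hepatocellular carcinoma list -0.053, miR-4489 -0.071, miR-92a-3p -0.022, miR-122-5p -0.16, miR-146a-5p -0.24, miR-23b-3p -0.063, miR-27b-3p -0.024, miR-23a-3p -0.33, miR-1323 -0.052, miR-518b -0.040, miR-371b-5p -0.25, miR-26a-5p -0.078, miR-29b-3p -0.38, miR-494-3p -0.19, miR-487b-3p -0.11, miR-7975 -0.21 and miR-7977 -0.10. Array weights gave the endothelial and angiogenic list -0.077, the MET-targeting list -0.0015, the raised in hepatocellular carcinoma list 0.017, the high-numbered list -5.3e-05, miR-122-5p -0.045, miR-146a-5p -0.15, miR-23a-3p -0.12, miR-498-5p 0.0024, miR-29b-3p -0.23, miR-487b-3p -0.051 and miR-7975 -0.13. The no-probe limit gave the endothelial and angiogenic list 0.0021 and the 14q32 list 0.043. Spike scaling gave the endothelial and angiogenic list -0.10, the MET-targeting list 0.16, the 14q32 list 0.16, miR-214-5p 0.11, miR-138-5p 0.11, miR-6742-5p 0.023, miR-146a-5p -0.029, miR-23a-3p -0.12, miR-498-5p 0.13, miR-371b-5p -0.042, miR-371b-3p 0.051, miR-29b-3p -0.17 and miR-7975 -0.0040. The haemolysis covariate without mock 7 gave the endothelial and angiogenic list -0.12, the p53-responsive list -0.0045, the MET-targeting list -0.0022, the raised in hepatocellular carcinoma list 0.016, the high-numbered list 8.6e-04, miR-122-5p -0.069, miR-146a-5p -0.19, miR-133b 0.018, miR-23a-3p -0.12, miR-498-5p 0.0015, miR-371b-3p 0.0019, miR-26a-5p -0.012, miR-29b-3p -0.32, miR-487b-3p -0.066 and miR-7975 -0.11. The estimated correlation without mock 7 gave the endothelial and angiogenic list -0.10, the p53-responsive list 0.0084, the MET-targeting list -0.0041, the raised in hepatocellular carcinoma list 0.016 and the high-numbered list 0.0011. Omitting the filter gave the p53-responsive list 0.022 and the MET-targeting list -0.015. Spike scaling without mock 7 gave miR-214-5p 0.16, miR-138-5p 0.13, miR-6742-5p 0.14, miR-146a-5p -0.011, miR-23a-3p -0.031, miR-498-5p 0.19, miR-371a-5p 0.10, miR-371b-3p 0.17, miR-29b-3p -0.17, miR-1185-1-3p 0.11 and miR-7975 -0.027. The haemolysis covariate gave miR-451a 0.12 (fixed by construction, since the index contains it), miR-146a-5p -0.054, miR-133b 0.070, miR-133a-3p 0.012, miR-371b-5p -0.030 and miR-29b-3p -0.010. The replicate block without mock 7 gave miR-122-5p -0.032, miR-146a-5p -0.093, miR-23a-3p -0.16, miR-498-5p 3.3e-04, miR-371b-3p 6.4e-04, miR-26a-5p -0.093, miR-29b-3p -0.27, miR-487b-3p -0.035 and miR-7975 -0.12. Median scaling without mock 7 gave miR-122-5p -0.045, miR-146a-5p -0.18, miR-23a-3p -0.20, miR-498-5p 0.024, miR-371b-3p 0.0024, miR-26a-5p -0.031, miR-29b-3p -0.33, miR-487b-3p -0.083, miR-7975 -0.19 and miR-7977 -0.071. Blank subtraction without mock 7 gave miR-146a-5p -0.15, miR-23a-3p -0.15, miR-371b-3p 0.0030, miR-26a-5p -0.027, miR-29b-3p -0.27, miR-487b-3p -0.025, miR-7975 -0.10 and miR-7977 -0.0087. The no-probe limit without mock 7 gave miR-146a-5p -0.085, miR-23a-3p -0.13, miR-26a-5p -0.023, miR-29b-3p -0.21, miR-487b-3p -0.010, miR-7975 -0.10 and miR-7977 -0.0087. Cyclic loess gave miR-371b-5p -0.057, miR-371b-3p 0.0018, miR-7975 -0.43 and miR-7977 -0.27. Omitting the background correction gave miR-29b-3p -4.3e-04. Leaving out 1 array gave the MET-targeting list -0.0041 to 0.036, the endothelial and angiogenic list -0.10 to 0.053, the high-numbered list -0.0079 to 0.0011, the p53-responsive list 0.0084 to 0.066, the raised in hepatocellular carcinoma list 0.016 to 0.17, miR-133a-3p -0.56 to 0.045, miR-133b -0.49 to 0.13, miR-146a-5p -0.085 to 0.064. It further gave miR-23a-3p -0.13 to 0.12, miR-26a-5p -0.023 to 0.32, miR-29b-3p -0.21 to 0.070, miR-371b-5p -0.021 to 0.047, miR-487b-3p -0.010 to 0.13, miR-498-5p -0.0095 to 2.5e-04, miR-7975 -0.10 to 0.30, miR-7977 -0.0087 to 0.40.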

Other observations

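The tests of red-cell lysis and of the scaling between arrays were chosen after the results were seen. Muscle miRNAs were bright on a few arrays of either group. miR-1-3p, named after its values were seen, reached a scanner brightness of 302 on mock 1, 430 on mock 2, 145 on cabozantinib 8 and 457 on cabozantinib 9, against 55.8 to 69.8 on the other 14, and miR-133a-3p was raised on the same 4 arrays (262, 611, 115 and 209). The C19MC cluster, specific to primates, was near the floor. Of 41 C19MC miRNAs, 7 were kept at the blank limit and 0 exceeded the limit from spots without a probe on 9 arrays. Only 4 of 46 probes of the 14q32 cluster and 3 of 9 of the miR-200 family did so, against 9 of 9 for let-7.

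For the 7 calls between the cabozantinib and mock groups with 18 arrays, 1 of 100 splits, the real one, gave as many, with 1 call as the highest other. For the 39 without mock 7 it was also 1 of 100, with 19 as the highest other. A random split thus rarely gave as many calls, although 100 splits cannot show a share below 1 in 100. The removal of mock 7 was chosen after the data were seen, and the splits do not bear on handling differences between the groups. With the haemolysis index as a covariate, the differences of the 29 lowered miRNAs kept a median of 0.85 times their size (0.68 to 1.21). The lowest ratio was that of miR-16-5p, and the count of calls dropped to 17. The index as measured thus took up a small part of most differences. The 29 were chosen as lower without the covariate, and the index rests on miR-451a and miR-23a-3p alone. The ratios therefore do not settle how far red-cell lysis accounts for the lower levels. The median difference of the 29, -0.41 with quantile normalization (median SE 0.082), was -0.30 under spike scaling (median SE 0.135) and -0.46 under median scaling. Of the 29, 22 stayed negative under spike scaling and 29 under median scaling, and miR-214-5p (0.16) and miR-138-5p (0.13) were among those that turned under spike scaling. The 29 were chosen as lower on these same arrays with quantile normalization, so these medians do not settle how far the scaling accounts for their lower level. The share of lower among all calls was 0.74 with quantile normalization, 0.47 under spike scaling (9 lower and 10 higher) and 0.89 under median scaling, so the scaling may account for the excess of lower over higher calls, which the 2 scalings leave open. An effect of cabozantinib on vessels or blood cells stays open as a hypothesis without a test here, and so does carry-over of platelets or leukocytes.

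A hypothesis was that miR-210-3p rises where miR-126-3p falls, as 1 graded response per mouse. Within the 9 cabozantinib arrays (normalized without mock 7) Pearson's r was -0.20 (exact permutation p = 0.593) and Spearman's rho -0.24 (exact permutation p = 0.528), with adjusted p values of 0.593 and 0.660 over 5 relations. Without the 2 arrays farthest from the median of miR-126-3p, r was 0.32. Within 8 mock arrays r was -0.47 (exact permutation p = 0.237) and rho -0.43 (exact permutation p = 0.299), while over all 9 mock arrays r was 0.48 (exact permutation p = 0.203) and rho 0 (exact permutation p = 1). With so few arrays the relation could not be decided.

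The relation of blank level between same-numbered arrays of the groups did not pass after adjustment. Over 9 pairs of same-numbered arrays Pearson's r was 0.78 (exact permutation p = 0.013, adjusted p = 0.066) and Spearman's rho 0.78 (exact permutation p = 0.017, adjusted p = 0.086) over 5 relations, and r was 0.67 without the 2 pairs farthest from the median.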
